A study of Homo sapiens and Drosophila melanogaster and Mus musculus with 23 samples.

How the data were processed

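RNA was measured by sequencing in 23 samples of 12 groups, per the labels. Total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name Bowtie 0.12.2 and the genome builds hg19, mm8, mm10, dm6 and GRCz11, without saying which served which table. The tool that counted reads and its annotation are not given in the sources used here; the column names end as RSEM's gene tables do. The deposited values are estimated counts per gene, not normalized: 20.4 to 21.0% of genes above 0 in a library had decimals, which arise when reads that fit several genes are divided between them. Strand is not stated for the counting, so overlapping and antisense genes cannot be told apart.

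Each of the 6 deposited tables was compared with the 293T table before any test was run. The tables labelled for HepG2, NIH-3T3, AB9, S2 and fission yeast held between 55754 and 57331 of its 57820 rows, lacking between 489 and 2066. Their 20 columns were read only for this comparison, in which 0 of 1133752 values differed, and went into no group. The tests planned for these 5 comparisons, and those across lines, were not run.

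In the 293T table, 27082 rows were at 0 in all 4 libraries and 0 rows had no gene name. Column names show the group of a library, not which labelled sample it is, so libraries were used as unpaired replicates numbered in column order; the names carry the numbers 2 and 3 in both groups, which no label says pair them. Libraries of a group differed by more than sampling noise: over genes with a summed count of at least 100, the chi-square per gene was 3.44 in KO and 1.60 in WT, and 16.4% and 9.49% of genes lay beyond the 95% limit against 5% by chance. All 4 libraries were kept, with n = 2 in each group. Mitochondrial genes took 7.04 to 7.32% of counts.

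Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr (minimum count 10), leaving 17912, and KO was compared with WT by the quasi-likelihood test of edgeR 4.0.16 with TMM scaling, in R 4.3.3. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and the standard error of a log2 fold change was its size divided by the square root of F. The biological coefficient of variation was 2.62%, with 2 residual and 8.89 prior degrees of freedom. Group values are means ± SD of TMM-scaled CPM. Against 0 counts, a fold was computed from a floor of 3 counts over the group; intervals and floors cover counting error only. The 27 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 4 tested members. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were alternatives. With an estimated correlation, camera's test has only the 2 residual degrees of freedom. Few lists could then be called, whatever their correlation.

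Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took METTL4, then, among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries, the 10 largest increases and the 10 largest decreases, leaving out rows named only by a clone or locus. It added up to 4 members of each list, the called ones with the smallest p or otherwise those with the smallest p. Some genes that the rule takes are not reported here. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter except rows at 0, a mean of at least 1 CPM, robust fitting, each library left out, and a change of at least 1.5-fold. Leaving out genes of the chromosome blocks, leaving out genes with decimals in their counts, a change of at least 2-fold, and a block on the numbers in the column names were chosen after seeing the data.

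Gene positions, GC content and transcript length came from GENCODE 29 (GRCh38), to which 52338 of 57820 rows matched by gene ID. As the files' build may be another, only gene order and chromosome were used. Blocks were runs of at least 20 windows of 31 neighbouring protein-coding genes, with log2 CPM above 1, whose median log2 fold change was beyond 0.35 in one direction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

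The edgeR steps were tested on simulated data, with counts of the 17912 genes drawn from the means, library sizes and dispersions of the 293T comparison. With 50 genes changed at each size, 88% were called at 1.25-fold, 92% at 1.5-fold, and 100% at 2-fold and at 4-fold. The share of false calls exceeded the nominal 5%: over 20 simulations with 200 changed genes it averaged 11.7%, from 4.8 to 19.6%. In 10 further simulations, added after these were seen, with as many changed genes as were called in the data (9237), it averaged 2.5%. These simulations took the called genes at their fitted fold changes as the truth, and all other genes as unchanged. The lower share thus depends on the number of changed genes chosen and is no check of the real calls. In a first simulation DESeq2 gave 2.75% false calls where edgeR gave 11.2%. A simulated shift of 1 list was called, with 0 of 26 unchanged lists called, and blocks of 60 genes planted in shuffled fold changes were found with 0 false blocks. In the list simulation genes varied independently and no gene outside the shifted list changed. It therefore cannot show how often lists are called falsely where genes are correlated or many genes change.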

Results

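The series was designed to ask how loss of METTL4, a methyltransferase of the MT-A70 family that acts on adenosine, alters RNA, with splicing named in its title. Its labels describe 23 samples in 12 groups, with knockout (KO) or knockdown (KD) and wild-type (WT) cells of 6 systems: the human lines 293T (embryonic kidney cells carrying SV40 large T antigen) and HepG2 (liver tumour cells), mouse NIH-3T3 fibroblasts, zebrafish AB9 fibroblasts, *Drosophila* S2 cells and fission yeast. Of the 6 deposited tables, 5 repeated the 293T table: all of their rows were human genes, and 0 of 1133752 values compared differed from the 293T value of the same gene. The 293T comparison, with 2 KO and 2 WT libraries, was therefore analysed, and the 5 others were not analysed here. The KO libraries held 35047840 and 36531745 estimated counts and the WT libraries 36266157 and 34902592. The table gives 1 value per gene, so splice isoforms were not analysed here. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

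The first question was whether the targeted gene was lower in the KO libraries. METTL4 (ENSG00000101574.10, chromosome 18) was measured at 6.39 ± 0.375 CPM in KO and 14.6 ± 0.682 CPM in WT (mean ± SD, n = 2 each), where CPM are TMM-scaled counts-per-million values. The KO libraries held 216 and 245 estimated counts of it and the WT libraries 507 and 522. The log2 fold change was -1.19 with a standard error of 0.0843, a 2.28-fold lower level (edgeR adjusted p = 4.9e-07). METTL4 mRNA was thus lower, and still detected, in both KO libraries.

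**Figure D1:**
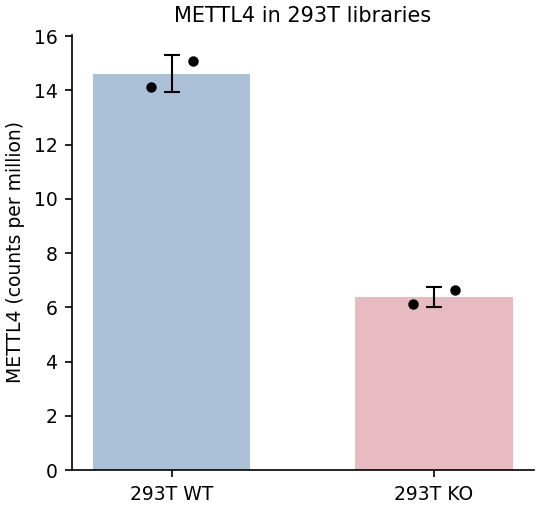
METTL4 in the 293T libraries. The vertical axis gives CPM, bars are group means, error bars are 1 SD and points are single libraries (n = 2 each). Both KO libraries lie below both WT libraries, with means of 6.39 and 14.6 CPM.

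Beyond METTL4, the KO cells differed from WT cells across much of the transcriptome. Effects of METTL4 loss cannot be told apart here from other differences between the KO and WT cells, such as their history. This holds for all genes and lists below. The largest increases among well-expressed genes included SAGE1 (11.0 ± 0.159 CPM in KO against 0.0856 ± 0.0423 in WT), a cancer/testis antigen, BEX1 (17.4-fold, 52.6 ± 1.6 against 3.02 ± 0.139 CPM) and TENM1 (8.28-fold, 140.6 ± 0.215 against 17.0 ± 0.284 CPM), which encodes a teneurin. The collagen gene COL12A1 rose from 2.48 to 18.1 CPM and the secreted glycoprotein gene LGALS3BP from 16.8 to 119.7 CPM. MKRN3, RAP1GAP2, PROCR and SAMD9 were also among the 10 largest increases, with log2 fold changes of 4.11, 2.69, 2.65 and 2.41. Among the decreases, the glutathione transferase gene MGST1 had 0 counts in both KO libraries and 19.9 ± 0.419 CPM in WT, at least 477.6-fold lower against a floor of 3 counts over the group. ZNF22 fell from 63.6 ± 0.639 to 0.0838 ± 0.0418 CPM, the cartilage collagen gene COL2A1 from 50.4 ± 0.326 to 0.222 ± 0.00675 CPM and the synaptic vesicle gene SV2A from 31.2 ± 0.648 to 0.152 ± 0.0542 CPM. ARMCX4, ITPKB, ZNF35, MARVELD2, CELF2 (an RNA-binding splicing regulator) and FAT3 completed the 10 largest decreases, with log2 fold changes from -7.45 to -4.42. For ZNF22, MKRN3 and TENM1, decimals in the estimated counts show that reads were shared with other genes, and ZNF22 also overlaps other genes over 45.3% of its length. None of the named genes in these 2 sets lay in the chromosome blocks described last.

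In total, 4417 genes were higher and 4820 lower in KO among 17912 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The typical called change was small, with a median of 1.29-fold, and 1420 higher and 1345 lower genes changed by at least 1.5-fold. DESeq2 called fewer, 2675 higher and 3186 lower, and with upper-quartile scaling more genes were higher (4989) than lower (4229). The 2 groups did not overlap for 75.2% of tested genes, against 33.3% by chance with 2 libraries in each group.

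**Figure D2:**
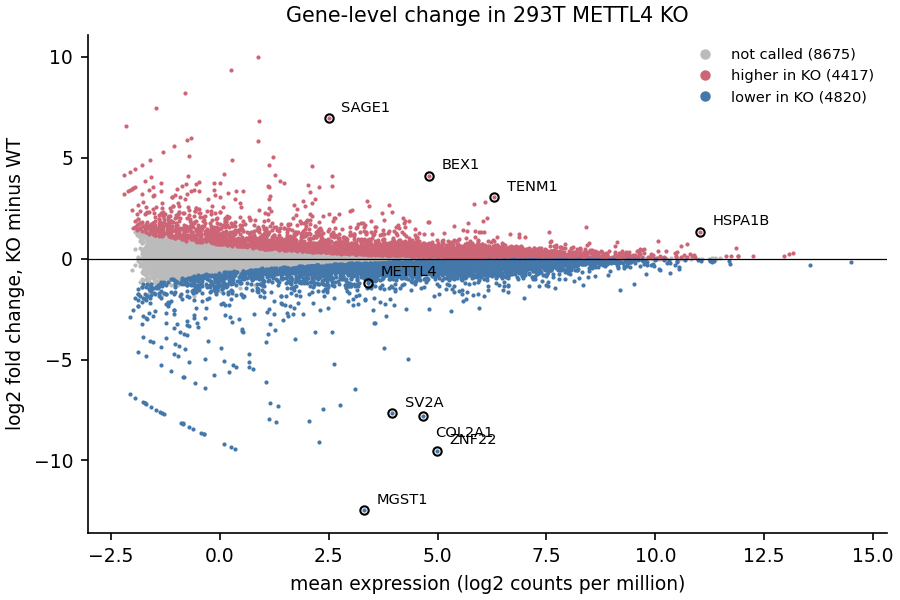
Gene-level change in 293T METTL4 KO. The horizontal axis is mean expression in log2 CPM and the vertical axis the fitted log2 fold change of KO minus WT; each point is 1 of 17912 tested genes, red where called higher (4417), blue where called lower (4820) and grey where not called, with 9 genes circled and named. Fitted changes of genes with 0 counts in a group, such as MGST1, depend on the prior count and are not measured folds.

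Gene lists fixed before the data were examined were then compared with all other tested genes. The clearest decrease was in cholesterol synthesis, where 20 of 22 tested genes fell and 1 rose. HMGCS1, at an early step of the mevalonate pathway, fell 1.95-fold, SQLE 1.81-fold, FDFT1 1.72-fold and LSS 1.91-fold; reads of HMGCS1, FDFT1 and LSS were partly shared with other genes. The list was called lower by camera with a preset correlation of 0.01 (adjusted p = 2.4e-06), and not with a correlation estimated from the data (adjusted p = 0.402 with an estimated correlation). That estimate was -0.044, below the preset, so a higher correlation does not account for the lost call. Camera's test with an estimated correlation has only 2 residual degrees of freedom, which leaves little power, here and for the lists below. Its unadjusted p for cholesterol synthesis was 0.0277. Of 26 tested p53 targets, 19 fell and 2 rose, among them CCNG1 (1.75-fold lower), SESN2 (1.64-fold), AEN (1.49-fold) and the death receptor gene TNFRSF10B (1.64-fold). Large T antigen, which 293T cells carry, binds p53. The camera adjusted p of the list was 2.0e-04 (adjusted p = 0.402 with an estimated correlation). SESN2 is also a member of the integrated stress response list below and counts in both. In the endoplasmic reticulum unfolded protein response, 17 of 21 genes fell and 3 rose. The chaperone gene HSPA5 fell 1.73-fold, XBP1 1.86-fold, CANX 1.41-fold and PDIA4 2.00-fold, the last in a chromosome 7 block of lower genes (camera adjusted p = 2.0e-04, adjusted p = 0.413 with an estimated correlation). Of 25 genes of the integrated stress response and amino acid synthesis, 18 fell and 4 rose, with DDIT4, which overlaps other genes over 41.2% of its length, 3.96-fold lower, the serine synthesis gene PSAT1 1.52-fold and SHMT2 1.45-fold (camera adjusted p = 0.00171, adjusted p = 0.402 with an estimated correlation).

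Of the lists of RNA-processing genes, camera with the preset correlation called only the SR and hnRNP splicing regulators, and that call was lost with an estimated correlation. Fry also called the U2 snRNP list (fry adjusted p = 0.0208) and the nonsense-mediated decay list (0.0305), but not the adenosine methylation factors (0.448). Of 42 SR and hnRNP splicing regulators, 28 fell and 3 rose, and 29 and 4 passed when adjusted over the list alone. HNRNPL fell 1.79-fold, HNRNPA3 1.72-fold, HNRNPA2B1 1.32-fold and HNRNPC 1.28-fold, all 4 with estimated counts that shared reads with other genes. The list was called lower (camera adjusted p = 2.4e-04, adjusted p = 0.457 with an estimated correlation). The list of U2 snRNP and 3 prime splice site recognition was not called (camera adjusted p = 0.281), with 7 members higher and 17 lower of 31. SNRPD1 fell 1.56-fold, with reads shared with other genes, and lay in a chromosome 18 block of lower genes, whereas SF3B3, SF3B5 and SF1 rose, with log2 fold changes of 0.32, 0.50 and 0.29. Among 20 adenosine methylation factors, METTL4 included, 7 rose and 6 fell, and the list was not called (camera adjusted p = 0.829). ZC3H13 fell 1.61-fold, in a chromosome 13 block of lower genes, and the demethylase gene ALKBH5, with reads shared with other genes, rose 1.47-fold, in a chromosome 17 block of higher genes. The list's median log2 fold change was 0.029 and its mean -0.05, which differ in sign. Nonsense-mediated decay factors and natural targets went both ways, with 10 of 23 higher and 8 lower (camera adjusted p = 0.731). Of 28 mitosis and G2/M genes, 17 fell and 2 rose, and 19 and 3 passed when adjusted over the list alone. CDC20 fell 1.48-fold and CENPE 1.45-fold, CKAP2 fell 1.91-fold within the chromosome 13 block, and AURKB rose 1.39-fold (camera adjusted p = 0.00413, adjusted p = 0.457 with an estimated correlation).

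Of the fixed lists, 3 were called higher by camera with the preset correlation, and 0 lists were called with an estimated correlation. Fry called 18 lists over both directions, but not the histones (fry adjusted p = 0.415). Of 51 tested replication-dependent histone genes, whose mRNAs mostly end without a poly(A) tail, 31 rose and 1 fell, and 34 and 1 passed when adjusted over the list alone. HIST1H4C rose 1.58-fold, HIST1H1E 1.67-fold and HIST1H3B 1.72-fold. HIST2H2AA4, whose reads were shared with other genes, rose 1.72-fold. Summed over the list, histone mRNA was 396.2 ± 4.7 CPM in KO and 280.4 ± 8.4 CPM in WT (camera adjusted p = 4.9e-06, adjusted p = 0.404 with an estimated correlation). Of 20 interferon-stimulated genes, 12 rose and 1 fell, with IFITM1 (overlapped by other genes over 32.5% of its length) 4.61-fold, IFIT5 2.30-fold and OAS3 2.38-fold higher (camera adjusted p = 2.5e-04, adjusted p = 0.402 with an estimated correlation). Of 5 tested muscle markers, 3 rose, of which only TNNT1 was above 1 CPM (15.8 against 6.94 CPM), with DES at 0.334 and MYOD1 at 0.595 CPM in KO. The muscle list was called (camera adjusted p = 0.0328), but not with an estimated correlation (adjusted p = 0.678 with an estimated correlation) or without KO replicate 1 (adjusted p = 0.0611). The immediate early genes were not called, with 11 of 23 higher and 2 lower (camera adjusted p = 0.0614), and were called without KO replicate 1 (adjusted p = 0.0172), with a mean of at least 1 CPM (adjusted p = 0.0334) and without genes of the chromosome blocks (adjusted p = 0.0256). FOS rose 3.42-fold and CTGF 3.64-fold, from 1.60 and 1.52 CPM in WT.

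No call was made by camera for the remaining lists. Heat shock chaperone genes split into 6 higher and 7 lower of 14 (camera adjusted p = 0.731): HSPA1B rose 2.53-fold, HSP90AA1 rose 1.42-fold within a chromosome 14 block of higher genes, HSPD1 fell 1.64-fold, these 3 with reads shared with other genes, and HSPH1 fell 2.12-fold at the edge of the chromosome 13 block. Hypoxia and glycolysis genes included 9 higher and 14 lower of 30, with BNIP3 (shared reads) 2.01-fold lower (camera adjusted p = 0.315). In fatty acid synthesis and lipid storage, 7 of 21 rose and 5 fell, with FADS2 2.60-fold lower and PLIN2 1.82-fold higher (camera adjusted p = 0.829). Of 22 NRF2 and oxidative stress genes, 10 rose and 9 fell, with HMOX1 1.90-fold and ABCC2 2.64-fold higher (camera adjusted p = 0.524). DNA replication and S phase genes were 10 higher and 12 lower of 34, with RFC3 1.71-fold lower within the chromosome 13 block and MCM5 1.23-fold higher (camera adjusted p = 0.731). Mitochondrial genome transcripts were 6 higher and 8 lower of 15 (camera adjusted p = 0.829), nuclear oxidative phosphorylation 14 and 8 of 51 (camera adjusted p = 0.517) and cytosolic ribosomal proteins 29 and 24 of 81 (camera adjusted p = 0.731). Extracellular matrix and myofibroblast genes were 12 higher and 7 lower of 28, among them FN1 1.55-fold higher and SPARC 13.5-fold lower (camera adjusted p = 0.418).

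The remaining lists hold markers of cell types. Neuronal markers were 6 higher and 1 lower of 12, with NEFM, which shared reads with other genes, 3.01-fold higher and INA 3.15-fold lower (camera adjusted p = 0.102). Epithelial markers were 2 higher and 2 lower of 6, with KRT8 (shared reads) 3.03-fold higher and CDH1 3.31-fold lower (camera adjusted p = 0.636). Genes associated with 293T were 4 higher and 3 lower of 10, with EYA1 4.04-fold and TERT 3.22-fold lower (camera adjusted p = 0.829). Hepatocyte markers were 1 higher and 1 lower of only 4 that passed the count filter (camera adjusted p = 0.867), and haematopoietic and endothelial markers were 1 higher and 0 lower of 6 (camera adjusted p = 0.983). In the haematopoietic list the median log2 fold change was -0.032 and the mean 0.371.

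**Figure D3:**
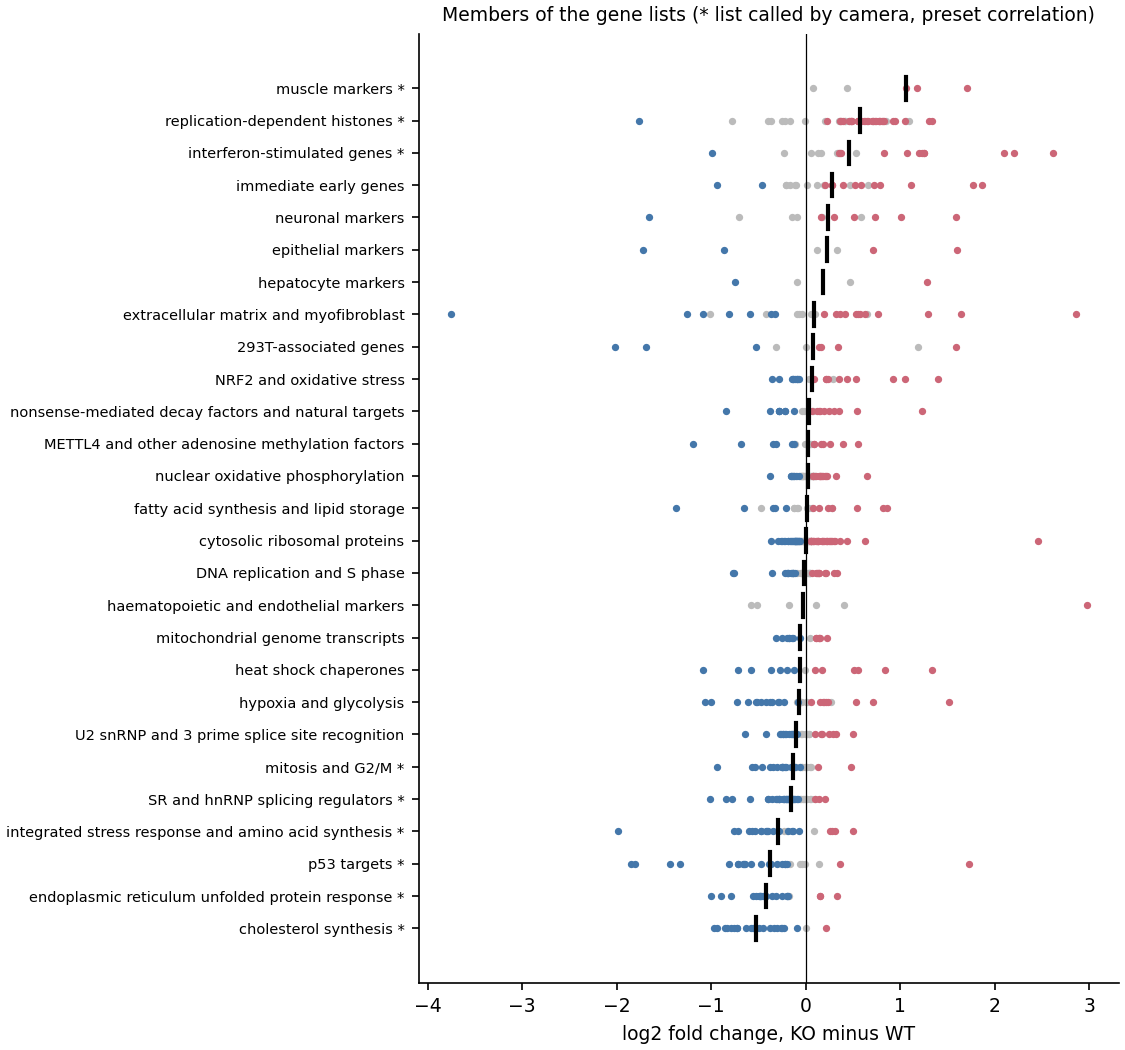
Members of the 27 gene lists. The horizontal axis is the log2 fold change of KO minus WT; each point is 1 tested gene, red where called higher, blue where called lower and grey where not called, black bars are list medians, and an asterisk marks the 9 lists called by camera with a preset correlation. Medians range from -0.524 for cholesterol synthesis to 1.06 for muscle markers.

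Neighbouring genes changed together in 8 blocks on 6 chromosomes, placed by the gene order of GENCODE 29 on GRCh38. On chromosome 13, 119 of 122 expressed protein-coding genes from HSPH1 to TMTC4 had lower values in KO, with a median log2 fold change of -0.68. Blocks of lower genes also ran from AGK to KMT2C on chromosome 7 (median -0.63, 43 genes), from SNRPD1 to KIAA1328 on chromosome 18 (median -0.58, 47 genes) and from KIAA1919 to KIAA0408 on chromosome 6 (median -0.50, 45 genes). Blocks of higher genes lay on chromosome 17 from FAM211A to SARM1 (median 0.54, 53 genes) and in 3 stretches of chromosome 14 (medians 0.42, 0.47 and 0.39, with 21, 25 and 34 genes). METTL4, also on chromosome 18, lay outside the blocks. Being outside them does not place it on an unshifted chromosome. Over all 170 expressed protein-coding genes of chromosome 18, block genes included, the median log2 fold change was -0.221 and 80.6% were lower in KO. Chromosome 21, which held no block, had a median of -0.181 over 106 genes, with 76.4% lower. Shifts were therefore not confined to the blocks. The blocks held 430 of the called genes, 142 higher and 288 lower.

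**Figure D4:**
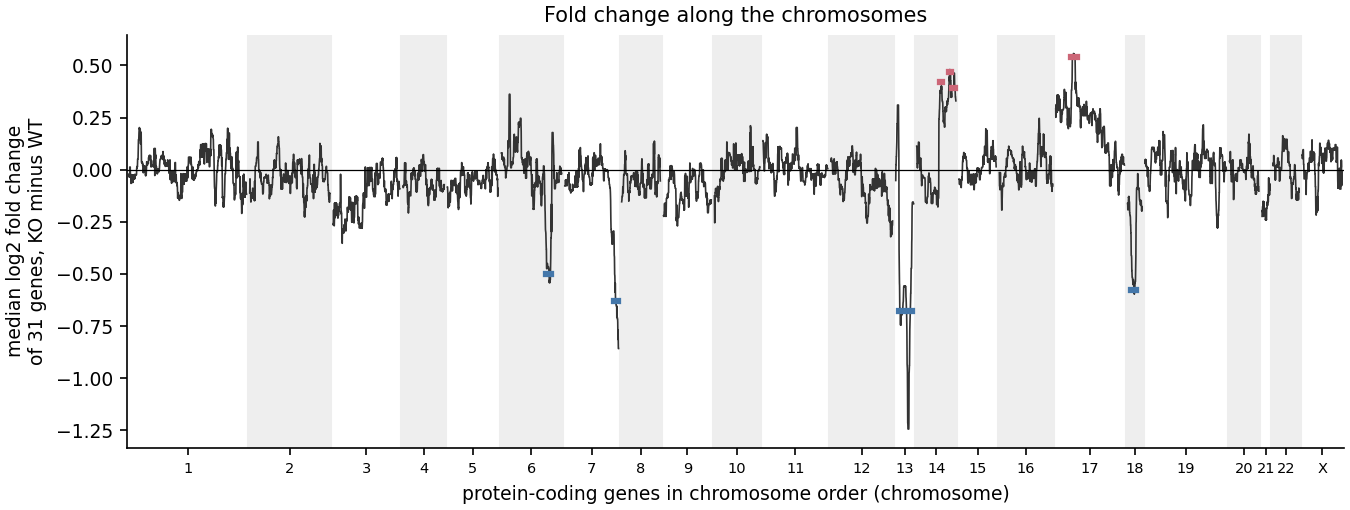
Fold change along the chromosomes. The horizontal axis orders 11778 expressed protein-coding genes by chromosome position, the line is the median log2 fold change of KO minus WT over 31 neighbouring genes, and thick bars mark the 8 blocks at their medians, red where higher and blue where lower in KO. The chromosome 13 block has a median of -0.68 over 122 genes.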

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

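Leaving out genes of the chromosome blocks, leaving out genes with decimals in their counts, the 2-fold limit and the replicate block were chosen after seeing the data. METTL4 stayed lower and past the threshold in all 8 of its alternatives, with log2 fold changes from -1.25 to -1.13. Of 943 values of the 118 other named genes, 934 kept direction and call; the 9 that lost the call belonged to DES, MYOD1 and CYP2E1, all near or below 1 CPM, and the cause was not tested. The numbers of higher and lower genes stayed within 1.5 times of 4417 and 4820 except in 3 settings. Upper-quartile scaling gave 4989 higher and 4229 lower, turning the balance from more lower to more higher, with a median shift of 0.0339 in log2 fold change. DESeq2 called 2675 higher and 3186 lower, and the cause was not tested; of these, 2674 and 3186 were also called by edgeR. A change of at least 1.5-fold left 1420 and 1345, and of at least 2-fold 756 and 586, by construction. With a library left out, an arm of 1 library is assumed to vary like the other group; counts were then 3868 to 4510 higher and 4258 to 4797 lower. Of 9 lists called by camera, 0 were called with an estimated correlation (3 had an unadjusted p under 0.05). That setting tests on 2 residual degrees of freedom, so the lost calls say little about the lists. Fry, which asks another question, called 18, including 8 of the 9. Histones were the called list that fry did not call (adjusted p = 0.415), and the cause was not tested. No called list changed direction. Lists that were not called did so in some settings, with these adjusted p: 293T-associated genes, 0.994 with a mean of at least 1 CPM and 0.933 without block genes; fatty acid synthesis, 0.0674 with fry and 0.975 without block genes; adenosine methylation factors, 0.448 with fry; hepatocyte markers, 0.415 with fry; and haematopoietic markers, 0.921 without block genes. With a library left out, fatty acid synthesis and adenosine methylation factors turned only without WT replicate 2 (0.971 for both), and ribosomal proteins only without KO replicate 1 (0.91); over all 4 such fits the adjusted p of these lists ran from 0.815 to 0.971, 0.82 to 0.971 and 0.253 to 0.926. The cause of these turns was not tested. Immediate early genes, not called in the main comparison, were called with fry (0.0305), with a mean of at least 1 CPM (0.0334), without block genes (0.0256) and without KO replicate 1 (0.0172). With a mean of at least 1 CPM, the muscle, hepatocyte and haematopoietic lists had fewer than 4 tested genes and gave no value. The alternatives planned for the 5 other systems were not run, since their tables repeat the 293T values. The column names carry the numbers 2 and 3 in both groups, though the labels do not say that they pair libraries, and same-numbered libraries did not deviate together (correlation across genes -0.1). With these numbers as a replicate block, which leaves 1 residual degree of freedom, 4354 genes were higher and 4740 lower, and the same 9 lists were called.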

Other observations

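The tests against shuffled gene order, other RNAs without a poly(A) tail, and S phase genes were chosen only after the results they bear on were seen, and the patterns themselves were noticed in these data. A small set of genes was detected in WT at 5 CPM or more and was near 0 (under 0.1 CPM) in KO: ARMCX4, DTX3L, ITPKB, MGST1, ZNF22 and ZNF700, with DTX3L and ZNF700 named after their values were seen. DTX3L, a ubiquitin ligase gene, had 677 counts over the WT libraries and 1 over the KO libraries (692-fold, 95% interval 124 to 27379). Only SAGE1 met the mirror condition, with 795 counts in KO and 6 in WT. For the set, loss of a chromosome segment reaching most of the 10 neighbouring genes was argued against. The median log2 fold change of the 10 neighbouring genes, over the 6 genes, was -0.084, with single medians from -0.254 (ZNF700) to 0.148 (ZNF22). A loss confined to a single gene, or reaching only a few of its neighbours, would leave these medians little changed, so these values cannot bear on it. Reads moving to a near-identical copy was also argued against as the cause for the set, since 16.7% of the genes (ZNF22) had decimals in their counts. Silencing of single genes, or loss of single genes or small segments, may remain. Whether any of these follows from METTL4 or from the history of the cells used was not tested.

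A chance order of genes was argued against as the source of the 8 chromosome blocks: 0 of 1000 shuffled orders gave as many genes in blocks as the 390 observed. Removing the trend with GC content and transcript length left at least 83.7% of each block's median. Blocks found with one KO and one WT library had at least 89.8% of their shift in the other KO and WT library, so differences of a single library do not account for them. A different copy number of these segments in KO and WT cells is a candidate explanation that stays open. It predicts a like shift at all expression levels. The medians of the most and least expressed genes of a block differed by up to 0.274 on the log2 scale, in a block of 21 genes. That was just beyond the limit of 0.25 set beforehand for each block, while all other blocks stayed under it, differing by at most 0.228. A different copy number thus cannot be told apart from regional regulation with these data.

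The rise of histone mRNA was set against 3 explanations. More carry-over of RNA without a poly(A) tail would raise other such RNAs too, but 16 of them had a median log2 fold change of 0.072 (quartiles 0.012 and 0.221) against 0.576 for histones. Single RNAs of the 16 ranged from -1.68 to 0.52, with 4 called higher and 2 called lower. More cells in S phase stays open: S phase genes went both ways, with a median of -0.015 (quartiles -0.144 and 0.102), while the mitosis and G2/M list was lower (median -0.135, 17 of 28 lower). A trend with GC content or length also stays open: 96.6% of the histone median was left after correction, but only 51.0% of the histone genes had values, so that check is void. A change in histone mRNA processing or decay may be involved and was not tested.

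A hypothesis of lower mRNA from genes with introns, as a splicing defect might give, was tested on 134 genes without introns outside the blocks and the histone list. Each was set against the median of genes with introns matched on GC content, length and expression. The median difference in log2 fold change was 0.137 (95% bootstrap interval 0.032 to 0.188). The bootstrap resampled genes, so its interval leaves out the spread between libraries or cultures. The median difference passed the limit of 0.1, which was set beforehand for the median alone, and the whole interval was positive. Because the interval also spans that limit and leaves out the spread between libraries, the hypothesis stays open.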
